A study of Schmidtea mediterranea with 6 samples.

How the data were processed

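Poly(A)-selected RNA-seq libraries of whole planarians were made with a TruSeq kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 1.8.3, Bowtie2 2.2.4 and DESeq2 without giving their roles. The transcript identifiers begin with SmedASXL, and the counting tool and any genome build are not given in the sources used here. The strain field gives a different CIW name for each sample, whereas the growth protocol names 1 clonal strain, CIW4, for all; the strain field was not used.

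Of 2 deposited tables, the first holds CPM per transcript, which the authors scaled to mapped reads, per the file headers, for each of 2 sequencing lanes per library. Its columns carry letters that are not in the labels, so they were used by group only, for 1 lane (lane 2), and 6 columns of this table were not used. The second table holds the authors' DESeq2 output: a log2 fold change with its standard error, a p-value and an adjusted p-value per transcript, as deposited, and 6 columns of signal values whose names match the sample descriptions. From the values, these deposited signal columns are read counts of both lanes divided by 1 size factor per library: all values (100%) were whole multiples of 1 step per column within 0.001. In myb-1 RNAi library 3 the step is close to 1. The lane 2 CPM, whose values were whole multiples of 1 step within 0.05 in 100% of cases, held 50.0% of these reads. A row named * that names no transcript was left out of library sizes and tests; it held 5.42% to 6.24% of the reads of a library. With this row the libraries held 32309070 to 43688794 reads, and 5 of the 6 fell short of the depth of over 40000000 reads that the labels state.

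CPM per sample were computed here from the deposited normalised counts, divided by each library's sum without the row *, since the deposited CPM columns could not be tied to single samples. This departs from the plan made before the data were examined, which was to use the deposited CPM. Transcripts with at least 0.5 CPM in at least 3 of the 6 libraries were tested with limma 3.58.1 (R 4.3.3; lmFit, then eBayes with trend and robust) on log2(CPM + 0.5), with group as the only term, p-values of both tails and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(CPM + 0.5) scale, which understates the change of low transcripts. Standard errors are limma's moderated ones. The samples have 1 read at 0.024 to 0.033 CPM, and 3 reads, the limit that a count of 0 allows, at 0.073 to 0.099 CPM. Exact 95% intervals of ratios are conditional binomial intervals on summed reads; they and the floors cover counting error only.

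The rule for named transcripts took the 2 largest rises and the 2 largest falls in log2 change past the threshold with a mean of at least 1 CPM and non-overlapping groups, since the tables give no gene names. For the same reason the 20 gene lists fixed before the data were examined (cell types, the epidermal lineage and general processes) matched 0 transcripts and were not tested. No genome or annotation was used here, so no coordinates, lengths or GC content are given. Reads shared between isoforms, paralogs or overlapping assembled transcripts could be split by the counting, and every count of transcripts carries that limit.

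No 2 libraries agreed within sampling noise: the chi-square of the reads of 2 libraries of 1 group, per transcript, was 3.28 to 49.3, where sampling noise alone gives about 1. The highest value, for control libraries 1 and 3, came mostly from 1 abundant transcript, SmedASXL_012104, which took 0.82% and 4.81% of their reads. The median absolute log2 difference between 2 libraries of 1 group was 0.100 to 0.146. The labels call the samples biological replicates. On simulated data with 200 changed transcripts among 25292 tested for this comparison, drawn with the real library sizes and a dispersion of 0.005, limma recovered 24% of the smallest simulated changes (1.25-fold), which it measured at a median of 0.28 on the log2 scale, 86% of 1.5-fold, 96% of 2-fold and 100% of 4-fold changes, and 1.29% of calls were false. The dispersion was the same for every transcript, and only transcripts with a control mean of at least 1 CPM were changed. edgeR's common biological coefficient of variation of the real reads was 7.26%.

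Alternatives were pseudocounts of 0.1 and 1, no filter and a filter of 2 CPM, scaling by TMM or by the median of ratios, no robust moderation, the replicate number as a term, each library left out, the thresholds 0.01 and 0.1, and count tests on the recovered whole reads with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. Left-out libraries kept the same set of tested transcripts. Added after seeing the data were the deposited CPM of 1 lane, cyclic loess normalisation, totals without 1 variable abundant transcript or without the fallen transcripts, the fit without 1 library of each group, the count at 2-fold, and the deposited p-values adjusted over the transcripts tested here. Figures were drawn with matplotlib 3.10.9.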

Results

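RNA from whole freshwater planarians, Schmidtea mediterranea of an asexual clonal strain, was sequenced after RNA interference by feeding. Planarians are flatworms that renew their tissues, the epidermis included, from dividing stem cells called neoblasts. Animals received double-stranded RNA against Smed-myb-1, a gene of the Myb family of transcription factors, or against unc22, a nematode gene used as a control. Both groups had 3 feeds over 1 week, and RNA was taken 6 days after the last feed. Each group had 3 samples, which the labels call biological replicates, of 30 animals each. The series asks what Smed-myb-1 contributes to epidermal differentiation, and the design makes 1 comparison, myb-1 RNAi against control RNAi.

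The 6 libraries held between 30311289 and 41145013 reads assigned to transcripts. Control libraries 1, 2 and 3 had 34522466, 35544455 and 36869837 reads, and myb-1 RNAi libraries 1, 2 and 3 had 41145013, 30311289 and 34430383. Reads were spread over 80979 assembled transcripts, of which 25832 reached the minimum abundance for testing and held 99.3% of the assigned reads. The values of the Smed-myb-1 transcript itself were not analysed here, because the tables pair the transcript identifiers with no gene names. Transcripts are therefore described by identifier, abundance and change, and a transcript is not equated with a gene. The groups parted along the first principal component of log2 abundance, which carried 45.6% of the variance. Pearson's r between log2 values across transcripts was 0.994 to 0.997 within groups and 0.989 to 0.992 between them.

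The largest effect of myb-1 RNAi was the near-complete loss of 8 abundant transcripts. Together they took 3376 ± 142 CPM (counts per 1000000 assigned reads; SD, n = 3) in control animals and 4.96 ± 0.57 CPM in myb-1 RNAi animals, which left 0.147% of the control level. Each was among the 728 most abundant transcripts of the control animals, at 196 to 820 CPM, and each fell to between 0.18 and 1.45 CPM. All 8 fell at least 64-fold in the limma test on log2(CPM + 0.5), with Benjamini-Hochberg adjusted p of 3.8e-05 or less. On that scale the smallest change among the 8 was -7.46 and the next transcript changed by -5.18. That order depends on abundance, because the next transcript went from 2043 control reads to 5, 405-fold lower by the ratio of reads with a 95% exact counting interval of 173 to 1247, inside the range of 241-fold to 2174-fold of the 8. These 8 were chosen by their fall in these same libraries, so their summed level describes them and is no separate test.

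The 2 transcripts with the largest fall on the log2(CPM + 0.5) scale were SmedASXL_073532 and SmedASXL_010535. SmedASXL_073532 went from 820 ± 22 CPM in control animals to 0.582 ± 0.128 CPM in myb-1 RNAi animals (SD, n = 3). This was 63 reads in the 3 myb-1 RNAi libraries against 87772 in the controls, or 1380-fold lower with a 95% exact interval of 1078 to 1795 that covers counting error only. SmedASXL_010535 went from 789 ± 127 to 0.864 ± 0.318 CPM, 877-fold lower with an interval of 717 to 1084. By the ratio of summed reads, 2 others of the 8 fell more than SmedASXL_010535, by 2174-fold and 1295-fold. On the log2(CPM + 0.5) scale, which understates falls to values this low, the changes were -9.57 (SE 0.08) and -9.19 (SE 0.21). The limma adjusted p was 1.4e-23 for SmedASXL_073532 and 3.8e-05 for SmedASXL_010535. In the authors' deposited table, their DESeq2 log2 changes were -10.39 (SE 0.20) and -9.76 (SE 0.37).

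**Figure D1:**
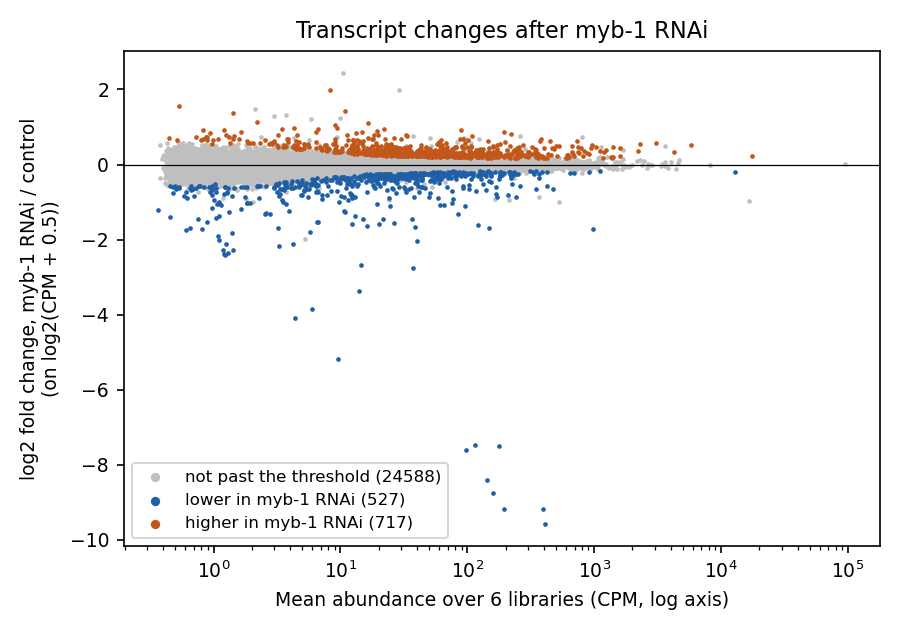
Each point is 1 of the 25832 tested transcripts, with its mean abundance over the 6 libraries (CPM, log axis) against its log2 fold change in myb-1 RNAi over control. The 527 transcripts called lower and the 717 called higher are coloured, and the 8 strong falls lie below -7 on the log2(CPM + 0.5) scale.

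Rises were smaller. Among called transcripts averaging at least 1 CPM, the 2 largest on the log2(CPM + 0.5) scale were SmedASXL_005696 and SmedASXL_019193. SmedASXL_005696 went from 3.03 ± 0.45 CPM in control animals to 13.4 ± 1.6 CPM in myb-1 RNAi animals (SD, n = 3), a log2 change of 1.98 (SE 0.12) with a limma adjusted p of 1.0e-09. SmedASXL_019193 went from 5.78 ± 1.57 to 16.03 ± 0.84 CPM, a log2 change of 1.43 (SE 0.16) with a limma adjusted p of 0.00086. For SmedASXL_019193 the call was lost when control library 1 was left out, at a log2 change of 1.47 and a limma adjusted p of 0.056, the highest over 23 alternatives, of which the lowest was 1.7e-11. For these 2 transcripts the authors' deposited table gave log2 changes of 2.18 (SE 0.15) and 1.505 (SE 0.26).

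**Figure D2:**
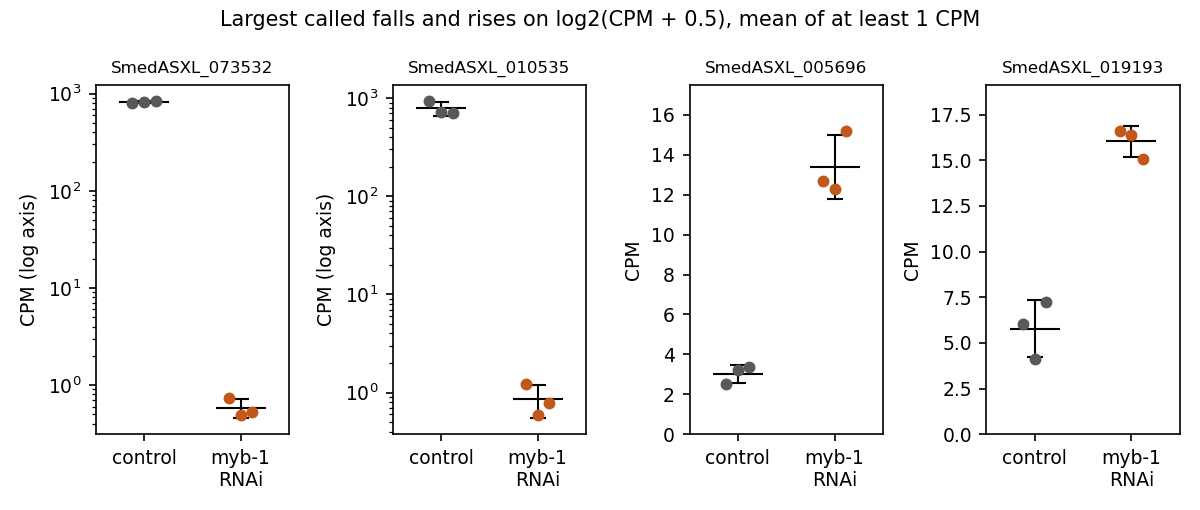
Abundance in each library (points, CPM) of the 2 transcripts with the largest called fall (log axes) and the 2 with the largest called rise (linear axes from 0), both ranked on the log2(CPM + 0.5) scale among transcripts averaging at least 1 CPM, with the mean and SD of 3 libraries per group. The groups do not overlap for any of the 4 transcripts.

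Over all tested transcripts, 527 fell and 717 rose in myb-1 RNAi animals at an adjusted p below 0.05 in limma, 4.82% of those tested. Most changes were small. The median fall was 1.34-fold, with quartiles of 1.22 and 1.61, and the median rise was 1.246-fold, with quartiles of 1.19 and 1.36. On the log2(CPM + 0.5) scale, called falls of at least 2-fold numbered 76 against 7 called rises. Called falls of at least 4-fold numbered 24, and the largest called rise was 3.94-fold, while rises that missed the threshold reached 5.39-fold. The 7 called rises depended on the pseudocount and the tool, with 23 at a pseudocount of 0.1, 30 in edgeR and 18 in the authors' deposited table. The falls of at least 2-fold there numbered 96, 106 and 76. By the ratio of reads, 1 called rise from 2 control reads was 55.0-fold, with a 95% exact counting interval of 14.9 to 460. The 3 libraries of each group did not overlap for 1243 of the 1244 called transcripts and for 20.7% of all tested transcripts, where chance gives 10%. Whether rises outnumbered falls depended on the scaling of the libraries. SmedASXL_012104, singled out after its values were seen, took 0.52% to 4.81% of the reads. With totals computed without this transcript, 698 rose and 781 fell, and with totals computed without the 527 fallen transcripts, 587 rose and 635 fell. The second of these totals leaves out falls only, which by itself lowers the log2 changes. Rises stayed in excess with TMM (794 against 543), median-of-ratios scaling (825 against 489) and cyclic loess (835 against 721). The counts also depended on single libraries, with 426 rises and 285 falls without control library 2, 396 and 338 without myb-1 RNAi library 2, 433 and 377 without myb-1 RNAi library 3, and 453 and 456 without control library 3, where 14 rises reached 2-fold.

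The transcripts that fell at least 2-fold held a measurable part of the reads. These 76 transcripts made up 0.656% ± 0.019 of the reads of control animals and 0.104% ± 0.007 of those of myb-1 RNAi animals (SD, n = 3). The 68 of them outside the 8 strong falls kept 32.6% of their control level, at 3182 ± 45 CPM in control and 1037 ± 65 CPM in myb-1 RNAi animals. All 717 risen transcripts together went from 10.4% ± 0.1 to 13.1% ± 0.1 of the reads. As above, these sets were chosen by their change in the same libraries.

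Falls and rises differed in the abundance of the transcripts they affected. Among 1619 transcripts averaging at least 100 CPM, 203 rose and 84 fell. Between 10 and 100 CPM, 416 of 8163 rose and 277 fell. Between 1 and 10 CPM the order turned, with 132 of 9984 falling and 85 rising, and under 1 CPM 34 of 6066 fell and 13 rose. All tested transcripts of these 2 classes leaned downward, with 39.7% and 39.9% of log2 changes positive, against 48.7% between 10 and 100 CPM and 51.5% from 100 CPM. Their median log2 changes were -0.039 and -0.045, and -0.011 and -0.004 after cyclic loess. The turn in order is therefore not particular to the called transcripts. Of the 76 falls of at least 2-fold, 10 were in the class from 100 CPM and 43 were under 10 CPM. Small changes are called more readily in abundant transcripts, so the shares of called transcripts in different classes are not comparable sizes of effect. With totals computed without SmedASXL_012104, falls outnumbered rises between 10 and 100 CPM, at 439 against 413, and with totals computed without the fallen transcripts they did so at 345 against 336. From 100 CPM the excess of rises shrank to 184 against 129 falls and 168 against 105 with these 2 totals, and to 184 against 148 with cyclic loess. Between 10 and 100 CPM rises stayed in excess with TMM (492 against 284), median-of-ratios scaling (506 against 244) and cyclic loess (502 against 393). In the other 3 classes the order stayed as given with both totals, TMM, median-of-ratios scaling and cyclic loess. After cyclic loess the excess of falls shrank to 146 against 121 between 1 and 10 CPM, and to 34 against 28 under 1 CPM.

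The 8 strong falls did not stop at a common remainder. The level left in myb-1 RNAi animals ranged from 0.046% of the control level (95% exact interval 0.028% to 0.072%, 19 reads) to 0.415% (0.352% to 0.486%, 154 reads), a 9.02-fold spread. The remainders differed beyond counting error (chi-square permutation test of reads between groups, drawn as 100000 tables with the same totals, p = 1e-05, the smallest these can give).

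**Figure D3:**
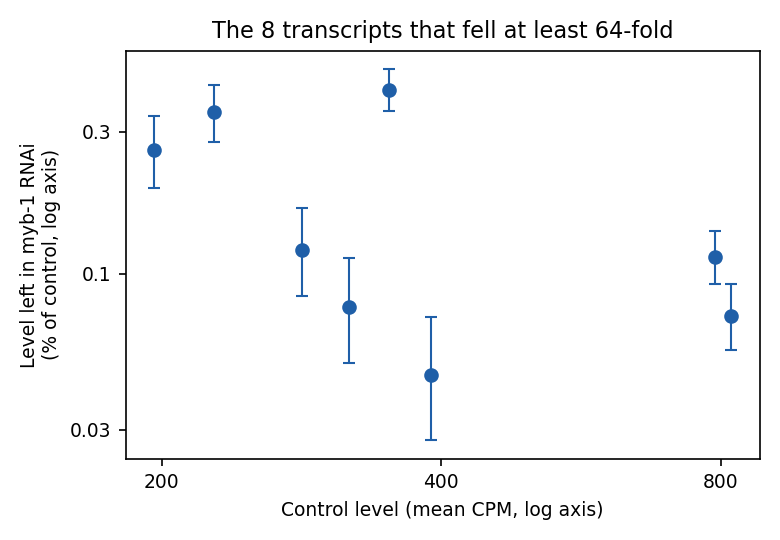
For each of the 8 transcripts that fell at least 64-fold, the level left in myb-1 RNAi animals as a percent of control (log axis, with 95% exact intervals for counting error) is plotted against its control level (mean CPM, log axis). The remainder ranges from 0.046% to 0.415%.

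The authors' deposited table called 1083 transcripts at a DESeq2 adjusted p below 0.05, of which 766 were higher and 317 lower in myb-1 RNAi. Of these, 978 (90.3%) were also called by limma with the same sign, and none with the opposite sign. The shared calls were 309 of the deposited falls and 669 of the deposited rises. The 8 strong falls were called in both. The share of calls that were rises was 70.7% in the deposited table and 57.6% in limma. Of the 527 falls called by limma, 35 had no adjusted p in the deposited table, where the lowest mean normalised count with an adjusted p was 35.1, and 183 had one that missed the threshold.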

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

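The fits without 1 library of each group, with cyclic loess, with other totals, on lane 2 alone and with the deposited p-values re-adjusted, and the counts at 2-fold, were chosen after seeing the data. The 8 strong falls were called lower under all 23 other fits, and no called transcript changed sign in any of them. The count of falls of at least 2-fold stayed within 1.5 times its value in all 23, at 55 to 106. The recovered reads gave 823 rises and 550 falls in edgeR and 868 and 441 in DESeq2. Leaving out 1 library gave 711 to 1454 changed transcripts, 396 to 929 rises, 285 to 525 falls, and 5 to 14 rises of at least 2-fold; the cause was not tested beyond the loss of a sample. Leaving out the first library of both groups, whose log2 values had the lowest Pearson r with the others of their group, gave 1960 changed transcripts and 1292 rises. Dropping the libraries least like their group narrows the spread within groups, so the higher count is no sign that more transcripts change. The deposited DESeq2 table gave 317 falls, and 313 when its p-values were adjusted over the transcripts tested here; the cause was not tested. An adjusted p below 0.01 left 685 transcripts, 384 higher and 301 lower. The 7 rises of at least 2-fold became 23 with a pseudocount of 0.1, 13 without robust moderation, 13 with the replicate block, 30 in edgeR, 12 in DESeq2, 18 in the deposited table and 29 with its p-values re-adjusted. SmedASXL_019193 was called in 22 of 23 fits. The replicate numbers were not taken to pair the samples, since the deviations of same-numbered libraries correlated at 0.08, 0.03 and 0.04, all under the 0.1 required; that 4 of 6 libraries correlated best with their own number is a hint the other way. The replicate block gave 722 rises and 527 falls. The alternatives fixed for the gene lists and for Smed-myb-1 were not run, because the tables pair the identifiers with no names. With these depths and 3 libraries per group, on simulated data 24% of the smallest changes, at a median of 0.28 on the log2 scale, were recovered; depth was not varied.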

Other observations

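The tests of freed reads, of residual reads and of left-out libraries, cyclic loess normalisation and the transcripts singled out by their values were chosen after the results were seen. Beside the 8 strong falls, 10 fallen transcripts averaged under 0.1 CPM in myb-1 RNAi animals, from control means of 0.71 to 19.1 CPM, and 1 of them had no read in any of the 3 myb-1 RNAi libraries. In the other direction, 1 risen transcript had 2 reads in the 3 control libraries together and 109 in the 3 myb-1 RNAi libraries, a ratio of 55.0 with a 95% exact counting interval of 14.9 to 460, at 1.06 ± 0.27 CPM (SD, n = 3) and a limma adjusted p of 3.6e-06. SmedASXL_012104, on average the transcript ranked 3 in abundance, took 0.82%, 1.22% and 4.81% of the reads of control libraries 1, 2 and 3, and 1.83%, 0.66% and 0.52% in myb-1 RNAi libraries 1, 2 and 3. Its log2 change of -0.98 had a limma adjusted p of 0.75.

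Among transcripts that did not pass the test, 7 were higher and 1 was lower in myb-1 RNAi by more than 1.2 on the log2(CPM + 0.5) scale. The 7 were 2.32-fold to 5.39-fold higher, with limma adjusted p of 0.069 to 0.48. Their sum was 21.1, 15.4 and 48.8 CPM in control libraries 1, 2 and 3 and 56.7, 100.5 and 140.5 CPM in myb-1 RNAi libraries 1, 2 and 3. In 6 of the 7, control libraries ranked 2, 1, 3 and myb-1 RNAi libraries 1, 2, 3 from lowest to highest, a combination found in 1.78% of all tested transcripts. That order is also the order of their own sums, so the comparison with 1.78% describes them and is no test. The 7 were chosen by size of change after seeing the data, and 2 of them were called in the deposited table and 0 by edgeR.

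The real grouping called 1244 transcripts, 717 higher and 527 lower, and the highest of the other splits of the 6 libraries called 0 in limma. At an unadjusted p below 0.05 the real grouping gave 3866 transcripts and the highest of the others 1290, and edgeR called 1373 and 0. Only 1 of the 10 splits, the real one, gave as many for each of the 3 counts, but 10 splits are too few for a share under 0.05. Every other split also mixes control and myb-1 RNAi libraries, so the group difference widens the spread within each side and lowers the counts. The other splits are thus no measure of what no effect would give, and no conclusion is drawn from them.

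Reads freed by the fallen transcripts are argued against as the whole cause of the many small rises, since 587 of the 717 (81.9%) stayed called higher with library totals computed without the fallen transcripts, while the other 130 did not. A small trend with abundance was present, with a median log2 change of -0.045 under 1 CPM and 0.007 from 100 CPM. The median rise was 0.317, so the size of this trend argues against it as the whole cause. After cyclic loess normalisation 692 of the 717 (96.5%) stayed called higher, which so small a trend made likely beforehand. Over the 9 ways to leave out 1 library of each group, the transcripts then called higher were followed in the left-out libraries. Their median change there, less the median change of all tested transcripts, was 0.667 to 1.03 times the same difference in the fit. Without library 1 of each group, 678 of the 717 (94.6%) stayed called higher. The 717 were chosen partly by the remaining libraries, and library 1 was picked as the least like its group. Most were thus likely to stay called, so the 94.6% by itself decides nothing. The fit without library 1 of each group called 1292 rises, which library 1 cannot have given. In the left-out pair of libraries 1, their median change less that of all tested transcripts was 0.295, against 0.297 in the fit, and 87.7% were higher than that median. For these 1292 transcripts the values argue against an axis carried by library 1 alone. The correlation test fixed beforehand, for an axis that also separates libraries of 1 group, decided nothing. Across transcripts, which are not independent, the log2 change correlated at -0.12 with the deviation of control library 1. With that of myb-1 RNAi library 1 it correlated at 0.01. The unequal spread of the libraries alone gives -0.17 and 0.14. The response to myb-1 RNAi itself, the difference the design names, stays open and may account for the rises.

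The reads left in myb-1 RNAi animals for the 8 strong falls could come from control libraries through misassigned barcodes, as the libraries carry the same lane names. Misassignment would leave the same percent of every transcript, but the remainders spanned a 9.02-fold range (permutation p = 1e-05, the smallest the 100000 draws can give), so it cannot be their only source, and the lowest remainder, with an exact interval up to 0.072%, bounds a uniform share. A low true level in myb-1 RNAi animals, from incomplete interference or from other cells, is a candidate source that was not tested.

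Pairs of consecutive identifiers were more frequent among called transcripts than in random lists. There were 26 such pairs among the 527 falls, 1 of them among the 8 strong falls, against a median of 11 and a highest of 25 in 10000 random lists matched on mean expression (adjusted p = 0.0002 over 2 tests, from the smallest p the lists can give), and 45 pairs among the 717 rises against a median of 27 and a highest of 46 (adjusted p = 0.0011). A hypothesis is that neighbouring identifiers mark assembled transcripts of 1 locus counted separately, so that the number of transcripts may exceed the number of genes. Over all 16977 consecutive tested pairs, called or not, the log2 changes correlated only weakly. Pearson's r was 0.086 and Spearman's 0.070, against a Spearman's of -0.002 for random pairs. These values give little sign that consecutive identifiers in general share their change. How the identifiers were numbered was not given, and neighbouring genes with a shared response would give the same excess. The pairs involve 9.11% of the falls and 12.1% of the rises.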
